A study of Mus musculus with 14 samples.

How the data were processed

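RNA was measured in 14 libraries from the mouse hippocampus (strain C57BL/6), taken from the subregions CA1, CA3 and dentate gyrus (DG). Per the labels' protocols, control tissue was homogenised directly, and dissociated tissue was first kept for 75 min in artificial cerebrospinal fluid with 1 mg/ml pronase, a mixture of proteases, then vortexed, centrifuged and triturated in fluid with 1% FBS. Both kinds of sample went through the same RNA isolation kit. There were 3 control and 3 dissociated libraries of CA1, 2 and 2 of CA3, and 2 and 2 of DG. The authors' sample table gives 1 mouse, 1 sequencing job and 1 date for all 14 libraries, so p-values here measure only the spread between tissue samples of 1 animal, and no batch could be separated.

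FastQC, cutadapt, kallisto and DESeq2 are named in the submitters' processing notes, without versions. Genome build, annotation release and sequencing strand are not given in the sources used here. The transcript tables hold estimated counts and TPM (transcripts scaled to a common total, corrected for effective length) from kallisto, per the file headers, for 58716 transcripts, every one with a coding range. Effective transcript lengths deposited by the authors in the same tables were used only to describe the files. The deposited gene table holds estimated counts of 22485 gene symbols, which were the transcript estimates summed by symbol and rounded by the authors, since each value lay within 0.5 of that sum. For 41 symbols the sum ran over more than 1 gene identifier. Because kallisto divides reads among transcripts with shared sequence, counts of near-identical copies, such as a ribosomal protein gene and its pseudogene, can move from one to the other. Of the transcripts, 53308 (90.8%) were found by identifier and version in GENCODE M21 with the same length, and coordinates of named genes are those of GENCODE M21 (GRCm38), matched by gene identifier.

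The gene table's estimated counts, already whole, were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr on the 6 groups of region and treatment (minimum count 10, minimum total 15), which left 13063 genes, and libraries were scaled with TMM. Dissociated and control libraries were compared by the quasi-likelihood F test in an additive model of region and treatment over all 14 libraries (10 residual degrees of freedom). CA1 with DG, CA3 with DG and CA1 with CA3 were compared in the same model. Treatment within each region, and the interaction of treatment with region, came from a model with 1 mean per group (8 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. The means and SDs printed are of CPM, counts divided by the library size scaled by TMM.

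The rule for naming genes was fixed before the data were examined. For treatment it took the 14 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM and the same direction of the group means in all 3 regions. For each region contrast it took the 6 highest and 6 lowest called genes with a mean of at least 5 CPM. Within regions it took the 5 smallest p-values among called genes. Members of 25 gene lists, also fixed beforehand, could be named as examples. Results of some genes that met these rules, and 1 test of an explanation, are not reported here. The lists cover stress, immediate early, inflammatory, plasticity and metabolic genes, quality measures, and markers of the cell types and subregions a hippocampal sample can hold. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with prior count 2), with Benjamini-Hochberg adjustment over 24 lists. Camera with an estimated correlation, fry and camera on count-based z-scores were run alongside. A list's score in a library is the mean log2 CPM of its members. Per-library values were compared between treatments by a two-sided exact permutation test within regions (720 assignments, smallest possible p 0.00278), adjusted over 29 values. The difference given with this test is the mean of the 3 within-region differences, so it can depart from the difference of the printed overall means.

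Depth ranged from 65887 to 6646655 estimated counts per library. A count of 0 allows up to 3 counts, which is 45.5 CPM in the shallowest library and 0.451 CPM in the deepest. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules. Where all libraries of a region or group were at 0, the fold is given as a lower bound against 3 counts over that region's or group's pooled counts. With 1 to 3 counts, the ratio of pooled CPM is given with its 95% exact Poisson interval. This interval, printed below as the 95% interval, covers only the counting error of the group with fewer counts. It leaves out the spread between libraries, so it is too narrow for the fold itself.

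The scripts were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 of 13063 genes changed. For dissociated vs control, 75 of 100 genes changed 4-fold and 23 of 100 changed 2-fold were recovered. For CA1 vs DG the recovered numbers were 68 and 9, and for treatment within CA1 43 and 1. Unchanged genes made up 2.97%, 3.75% and 8.33% of the calls. A list of 20 genes raised 2-fold was called, and 0 of 20 unchanged lists were. Genes were simulated independently of each other, so this does not show how often camera calls unchanged lists of correlated genes. In the real data the estimated correlation was 0.86 for the mitochondrially encoded genes.

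Alternatives covered DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, no filter and a stricter filter, an adjusted p under 0.1, other models and subsets, TPM with limma-trend, replicate blocks and leaving out each library. Restricting the test to protein-coding genes was not run, since every transcript in the tables has a coding range. Chosen after seeing the data were fits without the 3 dissociated libraries under 500000 counts (CA1 replicates 2 and 3, DG replicate 3), fits to the other 11 libraries thinned to 598775 counts each, and the list test on count-based z-scores. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for exact tests and plots.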

Results

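The study compared gene expression in hippocampal tissue that had been enzymatically dissociated with that in tissue homogenised directly, in the subregions CA1, CA3 and DG. Total estimated counts ranged from 1285654 to 6646655 in the 7 control libraries and from 65887 to 4782767 in the 7 dissociated libraries. The 3 control libraries of CA1 (replicates 1, 2 and 3) held 2311086, 6646655 and 2277596 counts, the 2 of CA3 (replicates 1 and 4) 1974845 and 2352153, and the 2 of DG (replicates 2 and 3) 1285654 and 6086605. The dissociated libraries with the same replicate numbers held 4782767, 135065 and 300812 counts in CA1 and 2498914 and 1193153 in CA3, and those of DG (replicates 3 and 4) 65887 and 598775. Depth was lower in dissociated libraries by 2.21 on the log2 scale on average (exact permutation p = 0.0333, adjusted p = 0.107). Of 22485 genes, the share with at least 1 count was 65.1 ± 2.73% in control and 51.6 ± 10.2% in dissociated libraries (SD, n = 7 each, exact permutation p = 0.00833, adjusted p = 0.0483).

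**Figure D1:**
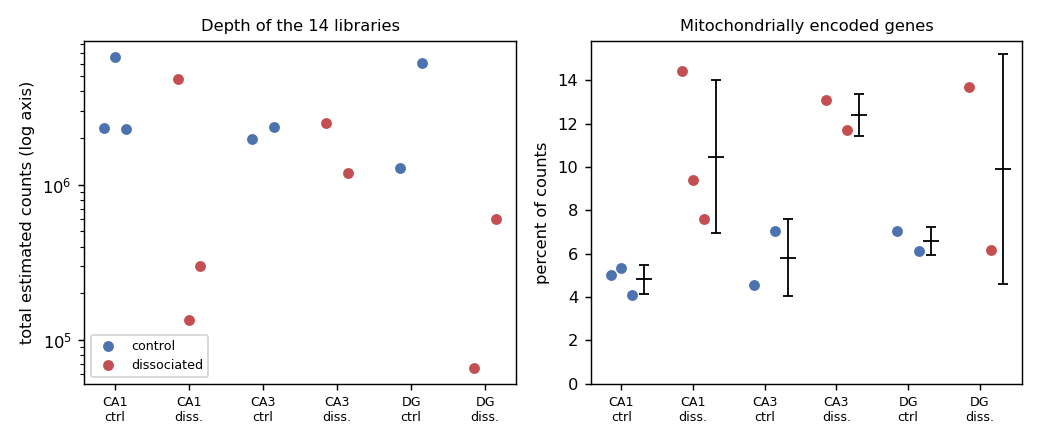
Left, total estimated counts per library on a log axis; right, percent of counts from mitochondrially encoded genes. Each point is 1 library of the region and treatment on the x axis, and black marks on the right give the group mean with its SD. Mitochondrial shares lay between 4.08% and 7.07% in control libraries and between 6.18% and 14.4% in dissociated libraries.

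The first comparison asked what dissociation does to the transcriptome across regions. Dissociated libraries were marked by higher transcripts of oligodendrocytes, the myelinating cells, of microglia, the resident macrophages of the brain, and of the mitochondrial genome. Of 13063 genes tested, 95 were called higher and 6 lower in dissociated than in control tissue (edgeR, adjusted p under 0.05), and 100 of the 101 had group means in the same direction in all 3 regions. The model pools the regions, so such agreement is partly built into the calls. The highest fold changes among the named genes included Mag, a myelin glycoprotein (log2 fold change 2.24 ± 0.41 SE; 74.4 ± 56.5 CPM in control and 301.4 ± 192.3 in dissociated libraries, SD, n = 7 each, edgeR adjusted p = 0.0106). Mpeg1, a macrophage pore-forming protein, was higher by 2.03 ± 0.29 (21.9 ± 6.22 and 90.9 ± 30.5 CPM, SD, n = 7 each, edgeR adjusted p = 0.00158). Plau, the urokinase plasminogen activator, was higher by 3.00 ± 0.53 (10.3 ± 5.33 and 112.7 ± 129.4 CPM, SD, n = 7 each, edgeR adjusted p = 0.0075).

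Mag (ENSMUSG00000036634) lies on chromosome 7 at 30899176 to 30914873, Mpeg1 (ENSMUSG00000046805) on chromosome 19 at 12460779 to 12465283 and Plau (ENSMUSG00000021822) on chromosome 14 at 20836660 to 20843385 (GRCm38). Other named genes above 2 on the log2 scale were Tlr2, a receptor of innate immunity (2.44 ± 0.53), Inpp5d, an inositol phosphatase of blood-lineage cells (2.39 ± 0.47), Cd68, a lysosomal glycoprotein of macrophages (2.19 ± 0.52), Fa2h and Mal of myelin (2.25 ± 0.49 and 2.01 ± 0.42), Ndrg1 (2.01 ± 0.40), Ctcfl (2.15 ± 0.46), Plekho2 (2.03 ± 0.48) and Zfhx3 (2.01 ± 0.42). Igf2bp2 (3.36 ± 0.70) and Gnaz (2.44 ± 0.50) also met the rule, but their counts did not follow library depth: Igf2bp2 had its highest count, 3925, in CA1 control replicate 1, and both held a larger share of the shallow libraries. Among the lower genes were Gm38394 (−2.46 ± 0.51), the potassium channel subunit Kcns2 (−1.50 ± 0.34), the ephrin receptor Epha6 (−1.28 ± 0.29), the mitochondrial fission protein Gdap1 (−1.03 ± 0.24) and the phosphatase Ppm1e (−0.97 ± 0.21).

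**Figure D2:**
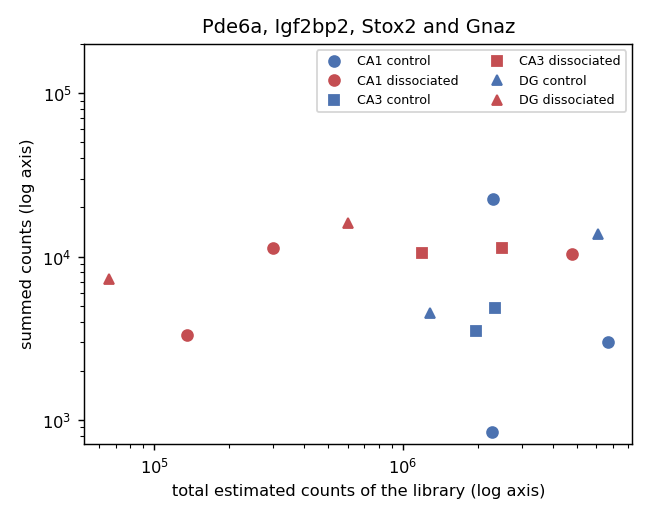
Summed counts of Pde6a, Igf2bp2, Stox2 and Gnaz in each of the 14 libraries against the library's total estimated counts, both on log axes, with the region as the shape and the treatment as the colour. The sum lay between 838 and 22604 counts in libraries of 65887 to 6646655 counts.

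The number of calls depended strongly on single libraries and on the shallow ones. It was 38, 40, 50, 52 and 42 higher genes without CA1 control replicates 2 and 3, CA3 control replicates 1 and 4 and CA3 dissociated replicate 4, and 205 without DG dissociated replicate 4. DESeq2 called 411 higher and 67 lower genes. Of the 19 named genes Plau, Mag and Mpeg1 were called in each of the 14 fits with 1 library left out, and the others in 1 (Gdap1) to 13 (Inpp5d) of them. Without the 3 dissociated libraries under 500000 counts, all 101 genes had the same direction, but 13 were called higher and 0 lower by edgeR, with Mpeg1 the 1 named gene among them. Several folds were then smaller, with a log2 fold change of 1.72 for Plau, 1.57 for Mag and 1.02 for Mal, against 1.91 for Mpeg1. On log2(TPM + 1) with limma-trend, 7 genes were higher and 48 lower, and RLE scaling gave 154 higher and 6 lower genes. The median log2 fold change of all genes was −0.11 with TMM and −0.01 with RLE.

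With all libraries, oligodendrocyte markers formed the list with the largest median. Without CA1 dissociated replicate 3 their median was 1.52, below that of the microglia markers, which was at least 1.59 in every fit with 1 library left out. Of 20 markers tested, 14 were called higher and 0 lower (18 higher adjusted over the list alone), with a median log2 fold change of 1.92. Mbp, the myelin basic protein, was at 804.1 ± 541.4 CPM in control and 2403 ± 1868 CPM in dissociated libraries (1.62 ± 0.27, edgeR adjusted p = 0.005). The iron carrier gene Trf was higher by 1.99 ± 0.28. The list test was called (camera adjusted p = 3.02e-32, adjusted p = 0.0321 with an estimated correlation). Between regions the same markers were lower in CA1 than CA3, with a median of −1.75 and 2 of 20 called (19 lower adjusted over the list alone, camera adjusted p = 7.06e-27, adjusted p = 0.159 with an estimated correlation). Of 8 markers of oligodendrocyte precursors 1, the growth factor receptor gene Pdgfra (1.46 ± 0.29), was called higher, and 5 were when adjusted over the list alone (median 1.38, camera adjusted p = 1.93e-06, adjusted p = 0.0327 with an estimated correlation).

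Of 20 microglia markers, 11 were called higher and 0 lower (19 higher adjusted over the list alone), with a median of 1.70 (camera adjusted p = 1.38e-25, adjusted p = 0.0304 with an estimated correlation). Csf1r, the receptor on which microglia depend for survival, was at 84.6 ± 23.0 CPM in control and 283.1 ± 87.6 CPM in dissociated libraries (1.69 ± 0.23, edgeR adjusted p = 0.00158). The fractalkine receptor gene Cx3cr1 was higher by 1.84 ± 0.26, the complement gene C1qb by 1.68 ± 0.25 and the lysosomal protease gene Ctss by 1.88 ± 0.29. These 4 genes were called in each of the 14 fits with 1 library left out. Without the 3 shallow libraries the medians of the oligodendrocyte and microglia lists were 1.22 and 1.49, with 1 and 4 members called. With 1 library left out, 9 to 16 oligodendrocyte and 7 to 16 microglia markers were called.

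**Figure D3:**
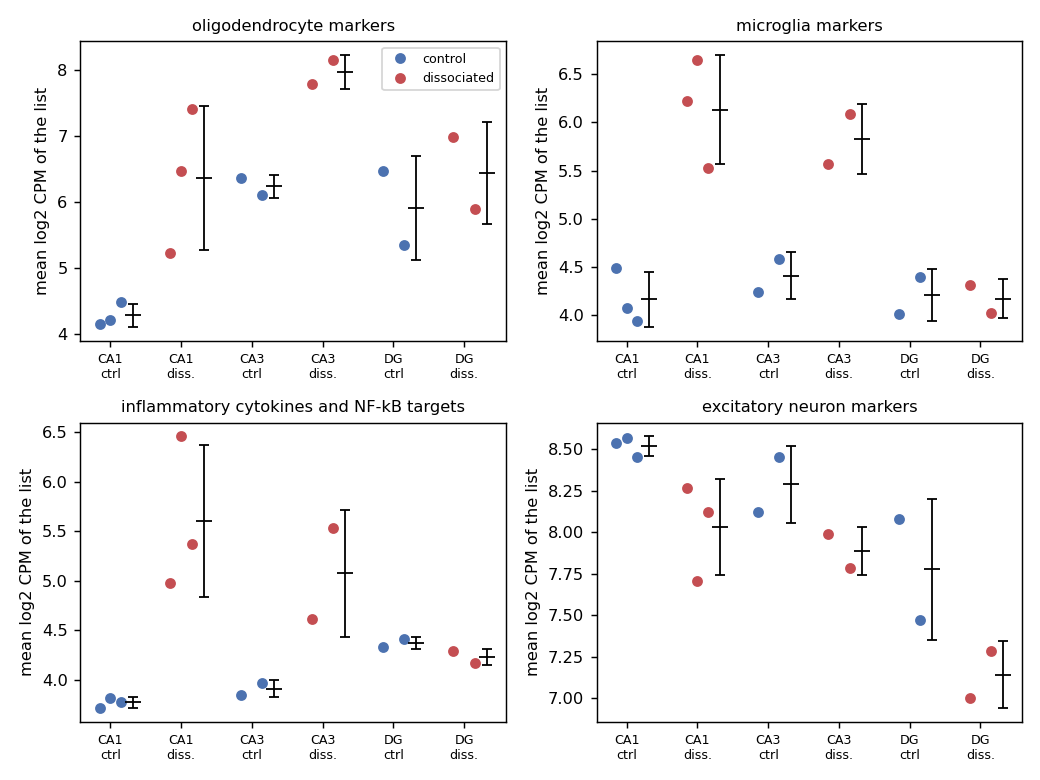
Mean log2 CPM of the members of 4 gene lists in each of the 14 libraries, by region and treatment, with the group mean and SD in black. The microglia score lay between 3.93 and 4.58 in control libraries and between 4.03 and 6.65 in dissociated libraries.

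Of 14 cytokine and NF-kB target genes, 4 were called higher (12 adjusted over the list alone; median 1.34, camera adjusted p = 2.12e-16, adjusted p = 0.0321 with an estimated correlation). The 4 were the cytokine genes Il1a (1.98 ± 0.38) and Tnf (1.90 ± 0.45), the inhibitor of cytokine signalling Socs3 (1.73 ± 0.28) and the NF-kB inhibitor Nfkbia (1.43 ± 0.29). The list's score was 4.28 and 4.17 in the dissociated and 4.33 and 4.41 in the control DG libraries. As the mean of the 3 within-region differences, it was higher by 0.95 in dissociated tissue (overall means 3.98 ± 0.28 and 5.06 ± 0.80, SD, n = 7 each, exact permutation p = 0.0167, adjusted p = 0.0691). The microglia score was higher by 1.12 in dissociated libraries, again as the mean of the within-region differences (overall means 4.25 ± 0.25 and 5.49 ± 0.98, SD, n = 7 each, exact permutation p = 0.0111, adjusted p = 0.0537). It was 4.32 and 4.03 in the dissociated and 4.01 and 4.40 in the control DG libraries. Of 33 immediate early genes, which neurons and glia induce within minutes of stimulation, 6 were called higher and 0 lower (12 adjusted over the list alone; median 0.52, camera adjusted p = 3.66e-13, adjusted p = 0.0397 with an estimated correlation). The 6 were Fos (1.00 ± 0.21), Fosb (1.39 ± 0.27), Jun (1.18 ± 0.23), Ier2 (1.18 ± 0.25), Atf3 (1.61 ± 0.32) and Maff (1.83 ± 0.42). Arc and Npas4, activity-dependent genes of neurons on that list, were not called (−0.12 and −0.31), though Npas4 was called lower with the replicate block within regions. Fry did not call the immediate early list (adjusted p = 0.077), and its score was higher by 0.37 in dissociated libraries (6.18 ± 0.44 and 6.55 ± 0.40, SD, n = 7 each, exact permutation p = 0.167, adjusted p = 0.302). With 1 library left out, 2 to 9 immediate early and 2 to 8 inflammatory genes were called. Without the 3 shallow libraries edgeR called 0 of the 33 immediate early and 0 of the 14 inflammatory genes, with medians of 0.55 and 1.11.

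With all libraries the 13 genes encoded on the mitochondrial genome were each called higher, with log2 fold changes from 0.83 for mt-Nd5 to 1.24 for mt-Nd3 and a median of 1.02 (camera adjusted p = 6.58e-23, adjusted p = 0.0397 with an estimated correlation). Their share of all counts was 5.62 ± 1.18% in control and 10.9 ± 3.19% in dissociated libraries (SD, n = 7 each, exact permutation p = 0.00556, adjusted p = 0.0483). In DG the share was 6.18% and 13.7% in dissociated replicates 4 and 3 and 7.06% and 6.14% in control replicates 2 and 3, so the DG rise rests on the library of 65887 counts. With 1 library left out all 13 genes stayed positive, with medians from 0.88 to 1.15, but the number called ranged from 1 to 13 and was 13 in 3 of the 14 fits. Without the 3 shallow libraries 2 of the 13 were called and the median was 1.12. Nuclear genes of oxidative phosphorylation had a median of −0.03 with 0 of 30 called, and 0 adjusted over the list alone (camera adjusted p = 0.215, adjusted p = 0.712 with an estimated correlation). Camera with the preset correlation called the list without CA3 control replicate 4 or DG dissociated replicate 4.

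The remaining glial and quality lists gave fewer calls. Of 16 astrocyte markers 0 were called (4 higher adjusted over the list alone) and all 16 had positive fold changes, with a median of 0.53. Camera called the list (adjusted p = 1.93e-06), but not with an estimated correlation (adjusted p = 0.24). The astrocyte median was 0.81 without the 3 shallow libraries, with all 16 positive and 0 called. Camera also called the list of 76 cytosolic ribosomal protein genes, with 0 genes called either way, 73 positive and a median of 0.40 (camera adjusted p = 1.35e-18, adjusted p = 0.24 with an estimated correlation). Within DG their median was −0.27, with 23 of 76 positive. It called the 5 red blood cell markers too, with 0 genes called (1 higher adjusted over the list alone) and a median of 1.13 (camera adjusted p = 0.0178, adjusted p = 0.247 with an estimated correlation). Neither list was called with an estimated correlation. The red blood cell list was also not called in 5 of the 14 fits with 1 library left out. Of 16 heat shock genes and chaperones 1 was called higher, Cryab (1.87 ± 0.39), a small heat shock protein that oligodendrocytes also express (2 higher adjusted over the list alone, median 0.03, camera adjusted p = 0.0506). Camera called the heat shock list with RLE scaling (median 0.12), with upper-quartile scaling (0.07) and in 4 of the 14 fits with 1 library left out. It was not called with an estimated correlation, by fry or without the 3 shallow libraries, where its median was −0.09. Of 14 hypoxia and glycolysis genes 1 was called higher, the glucose transporter Slc2a1 (1.23 ± 0.27, with 1 higher adjusted over the list alone, median 0.08, camera adjusted p = 0.129, adjusted p = 0.458 with an estimated correlation). Camera with the preset correlation called this list without CA1 dissociated replicate 2.

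Genes of neurons gave few calls. Of 35 genes of long-term potentiation and plasticity, 0 were called over all genes by edgeR, and adjusted over the list alone 4 were lower and 1 was higher (median −0.26, camera adjusted p = 0.294). With 1 library left out, 0 to 4 of them were called lower and 0 to 1 higher over all genes. Gria2, an AMPA receptor subunit, had the smallest p among them (−0.78 ± 0.19; 1023 ± 273.2 CPM in control and 587 ± 104.8 in dissociated libraries, edgeR adjusted p = 0.0617). Gria2 was called lower by DESeq2, by edgeR with the replicate block within regions, and by edgeR without DG control replicate 2 (−0.86) or DG dissociated replicate 4 (−0.85). Of 13 excitatory neuron markers 0 were called by edgeR (1 lower adjusted over the list alone), with a median of −0.34 (camera adjusted p = 0.45), while fry, which tests the direction of the list alone, gave an adjusted p of 0.0181. The list's score was lower in every dissociated than in every control library of the same region in all 3 regions (8.24 ± 0.39 and 7.74 ± 0.45, SD, n = 7 each, exact permutation p = 0.00278, the smallest possible, adjusted p = 0.0483).

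No member was called in the lists of inhibitory interneuron (12 tested, median −0.39), endothelial (13, 0.45), pericyte and smooth muscle (6, 0.40), choroid plexus and ependymal (4, −1.0), CA1 (9, −0.87), CA2 (7, −0.68), CA3 (9, 0.78) and DG granule cell markers (13, 0.00). The same held for genes of the unfolded protein response (14, −0.08) and for dendritic and neuropil-localised mRNAs (20, −0.05). Adjusted over the list alone, 1 choroid plexus and ependymal marker was lower and none of the others was called. With all libraries none of these lists was called by camera, with adjusted p between 0.0506 and 0.687, and for the unfolded protein response and neuropil lists, as for the nuclear oxidative phosphorylation genes, camera's direction was opposite to the median. Without the 3 shallow libraries the neuropil list's median was 0.28, with 15 of 20 members positive, and camera called it, as it did the CA1 markers (median −0.61, 0 of 9 positive). With 1 library left out, camera called the CA3 markers without CA3 control replicate 4, DG control replicate 2, CA1 dissociated replicate 2 or CA3 dissociated replicate 1, while their median was 0.14 without CA1 dissociated replicate 3. It called the CA1 markers without DG control replicate 3 or DG dissociated replicate 3, the granule cell markers without DG control replicate 3 and the endothelial markers without CA3 dissociated replicate 1. On count-based z-scores camera called the CA1 markers (adjusted p = 0.00833), the endothelial markers (adjusted p = 0.0439) and the plasticity genes (adjusted p = 0.0109). All these calls used the preset correlation. With an estimated correlation and all libraries, camera adjusted p lay between 0.577 (CA3 markers) and 0.734 (neuropil list) for the CA1, CA3, neuropil, granule cell, endothelial and plasticity lists. Only 2 peripheral leukocyte markers had enough counts to be tested, and neither was called (median 0.34).

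**Figure D4:**
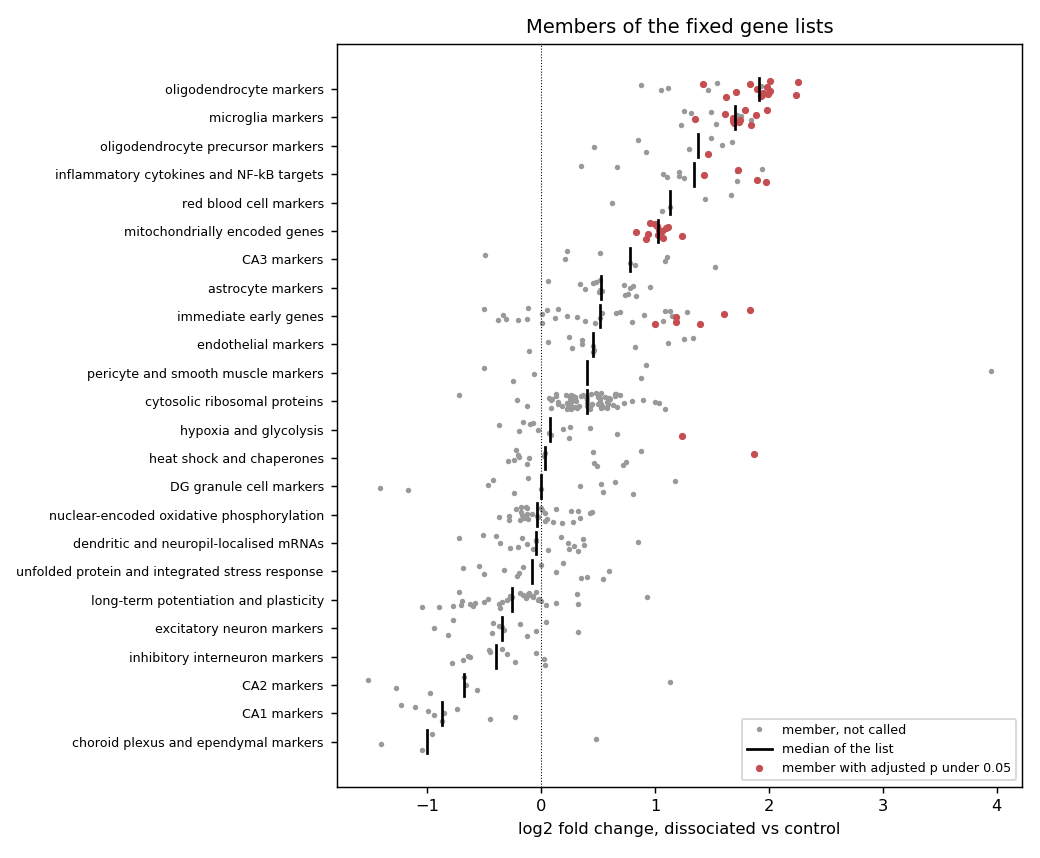
Log2 fold change, dissociated vs control, of each tested member of the 24 lists with a list test, red where the edgeR adjusted p was under 0.05 and grey otherwise, with the list's median as a black bar. Medians ran from −1.0 for choroid plexus and ependymal markers to 1.92 for oligodendrocyte markers.

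Treatment was then compared within each region. In CA1, 25 genes were called, all higher in dissociated tissue (edgeR; 1464 at an unadjusted p under 0.05), among them 7 oligodendrocyte and 7 microglia markers. Among the smallest p-values were those of Selplg, a selectin ligand of leukocytes and microglia (2.84 ± 0.43), Trf (2.58 ± 0.39), Ctss (2.45 ± 0.41) and C1qb (2.16 ± 0.37). In the CA3 libraries, 24 of these 25 genes had the same direction, and in the DG libraries 20. Of all 13063 genes, 6041 had positive fold changes in CA3 and 5062 in DG. Markers of 1 cell type can move together, so the 25 genes are not independent of each other. The CA1 groups include CA1 dissociated replicate 3, whose score of CA1 markers was 2.93 against 7.41 to 8.24 in the other CA1 libraries, and without it 7 genes were called and Trf was at 2.14. The CA1 count was 0 without CA1 control replicate 2 or 3 or without CA1 dissociated replicate 2, and 0 without the 3 shallow libraries, which leaves 1 dissociated CA1 library.

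In CA3, 0 genes were called by edgeR (523 at an unadjusted p under 0.05), and 0 by DESeq2 or limma-voom. The list medians in CA3 were nevertheless 1.77 for oligodendrocyte and 1.47 for microglia markers, with 16 and 10 members higher adjusted over the list alone, and 2.34 and 2.17 in CA1, with 20 and 19. In DG the medians were 0.90 and 0.98, with 0 members called either way. There 17 and 14 of the 20 members were positive, and the mean log2 fold changes were 0.32 and −0.25. Microglia scores in DG overlapped, at 4.32 and 4.03 in dissociated and 4.01 and 4.40 in control libraries. The median of all genes in DG was −0.27.

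In DG, 21 genes were called, 5 higher and 16 lower, of which 8 had the same direction in CA1 and 13 in CA3. The ribosomal protein pseudogene Rps12-ps3, which shares sequence with Rps12 and is therefore uncertain, had 1172 counts in the control libraries and 0 in the dissociated ones, at least 35.2-fold lower. Dbnl, an actin-binding protein gene, had 599 and 0 counts, at least 18.0-fold lower. Both bounds rest on DG dissociated replicate 4, the deeper of the 2 dissociated libraries, and without it were 3.49-fold for Rps12-ps3 and 1.78-fold for Dbnl. Vps29, a retromer subunit gene, had 715 and 2 counts, a ratio of 32.2 (95% interval 8.92 to 266.1, counting error only). Without DG dissociated replicate 4 none of these 3 genes was called and Vps29 was at −2.55 on the log2 scale, and without DG control replicate 2 Dbnl and Vps29 were not called. The actin genes Acta1 and Acta2 were higher, with Acta1 at 4235 CPM (279 counts) in DG dissociated replicate 3 and 31.7 CPM in DG dissociated replicate 4. Without DG dissociated replicate 3 their log2 fold changes were 2.42 and 3.92 and neither was called, nor was either without DG control replicate 2 or 3. The DG count was 1 without DG control replicate 2, and 0 with limma-voom or with the DG libraries alone.

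The test of whether the treatment difference itself varied between regions called 0 genes (edgeR interaction term, smallest adjusted p 0.0865; 1112 genes at an unadjusted p under 0.05). DESeq2 called 28 genes and limma-voom 0. Compared directly, the treatment difference in CA1 exceeded that in DG by a median of 1.56 for microglia markers and 1.78 for oligodendrocyte markers (camera adjusted p = 0.00252 and 0.021), but neither was called with an estimated correlation (adjusted p = 0.831 for both).

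The second question was how the regions differed. CA1 and DG were separated by 530 genes, 259 higher and 271 lower in CA1 (edgeR), with textbook subregion markers among them. Of 9 CA1 markers 8 were called higher in CA1 than DG (8 adjusted over the list alone; median 4.26, camera adjusted p = 2.09e-05, adjusted p = 0.528 with an estimated correlation), including Nov, a matricellular protein gene (7.88 ± 1.10; 260.2 CPM in CA1 and 4.55 in DG). Of 13 DG granule cell markers 10 were called lower in CA1 (13 adjusted over the list alone; median −3.63, camera adjusted p = 7.31e-19, adjusted p = 0.00902 with an estimated correlation), among them C1ql2, a synaptic C1q-like protein gene (−7.74 ± 0.60; 1.70 CPM in CA1 and 358.1 in DG, edgeR adjusted p = 2.58e-08) and the desmosomal gene Dsp (−7.16 ± 0.72). C1ql2 lies on chromosome 1 at 120340582 to 120343174 and Nov on chromosome 15 at 54745702 to 54754039.

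Several other named genes had no counts in the DG libraries, so their folds are lower bounds. The cadherin gene Cdh6 was at least 39.4-fold higher in CA1, the serotonin receptor gene Htr5b at least 37.9-fold, the interneuron peptide gene Vip at least 29.5-fold and the estrogen receptor gene Esr1 at least 23.3-fold. These bounds rest on DG control replicate 3, the deepest DG library, and without it were 9.56-fold, 9.21-fold, 7.15-fold and 5.65-fold. Crhbp, a binding protein of corticotropin-releasing hormone, had 492 counts in CA1 and 1 in DG, a ratio of 240.3 (95% interval 43.1 to 9492). Lower in CA1 were also Pcp4, a calmodulin-binding protein gene (−6.83 ± 0.96), and Htra4, with 3 and 142 counts (ratio 96.9, 95% interval 33.2 to 469.9). Rps12 had 0 counts in CA1 and was at least 108.5-fold lower there (64.7-fold without CA1 control replicate 2, the deepest), but reads it shares with its pseudogene make this value uncertain, and DESeq2 did not call it. The count of 530 was 199 without DG control replicate 3, where Cdh6, Htr5b, Vip and Esr1 were not called.

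CA3 and DG were separated by 231 genes, 116 higher and 115 lower in CA3 (edgeR). Of 13 granule cell markers 9 were called lower in CA3 (11 adjusted over the list alone; median −3.31, camera adjusted p = 4.97e-24, adjusted p = 0.00348 with an estimated correlation). Named genes lower in CA3 were the glutamate receptor gene Grm2 (−7.23 ± 0.76), C1ql2 (−7.07 ± 0.65) and Dsp (−6.46 ± 0.76). Mylk3, with 0 counts in CA3, was at least 65.5-fold lower (45.1-fold without CA3 dissociated replicate 1, the deepest), though DESeq2 did not call it. These bounds leave out its wide spread in DG (28.8 ± 41.5 CPM, SD). Mylk3 was not called without DG control replicate 3, CA3 dissociated replicate 1 or DG dissociated replicate 4, and was at −7.19 (log2) without the last. Igsf9 had 2 and 158 counts (ratio 78.8, 95% interval 21.8 to 650.9). Acta1 was called with all libraries, but not with RLE scaling and in only 3 of the 14 fits with 1 library left out, and it was at −1.31 without DG dissociated replicate 3. The collagen gene Col11a1 was higher in CA3 (6.85 ± 0.82), as were Crhbp (341 counts against 1, ratio 341.8, 95% interval 61.3 to 13500), Krt73 (at least 31.4-fold), Vip (at least 30.7-fold), Htr5b (at least 30.1-fold) and Esr1 (at least 21.7-fold). Without DG control replicate 3 the last 4 bounds were 7.62-fold, 7.46-fold, 7.30-fold and 5.27-fold. Of the 14 fits with 1 library left out, Krt73 was called in 4, Vip in 7, Mylk3 in 11, Htr5b and Igsf9 in 12 and Esr1 in 13. The count of 231 was 56 without DG control replicate 3 and 564 without DG control replicate 2.

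Markers of CA3 were not called between CA3 and DG. Of 9 CA3 markers 0 were called between CA3 and DG (median 0.02, camera adjusted p = 0.918), and 7 of 9 CA1 markers were called higher in CA3 than DG (8 adjusted over the list alone; median 3.93, camera adjusted p = 0.0871). Fibcd1, a marker of CA1 pyramidal cells, was at 864.4 and 715.5 CPM in the control and dissociated CA3 replicates 1, at 277.2 CPM in CA3 control replicate 4 and at 0 in CA3 dissociated replicate 4, where 0 counts allow up to 2.51 CPM. The CA3 marker Bok was at 423.2 CPM in CA3 dissociated replicate 4 and 135.6 CPM in CA3 control replicate 4, but also at 206.1 CPM in CA1 dissociated replicate 3 and 222.5 CPM in DG control replicate 2. Its log2 fold change between CA3 and DG was 0.34, and 2.81 without DG control replicate 2 but −0.36 without CA3 control replicate 4. It was called in 0 of the 14 fits with 1 library left out. In CA1 dissociated replicate 3 the CA1 markers Wfs1 and Fibcd1 were at 13.3 and 6.65 CPM, against 311 to 940.9 and 482 to 576 CPM in the other CA1 libraries. All libraries were kept in the groups the labels give.

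**Figure D5:**
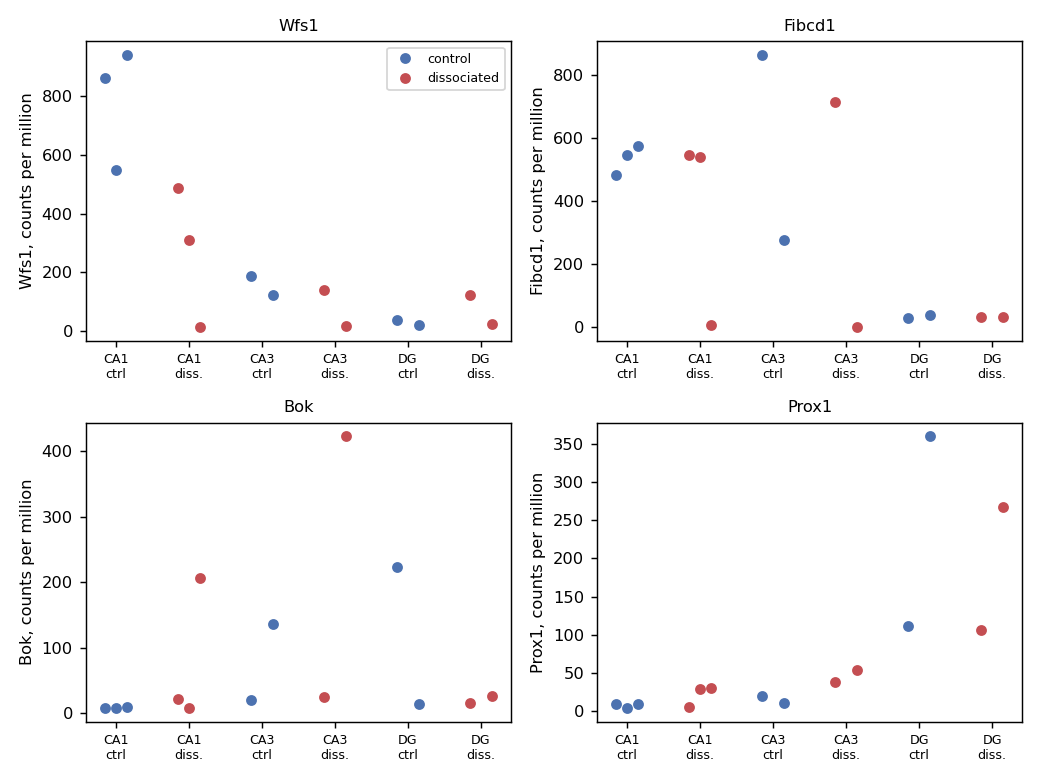
CPM of the CA1 markers Wfs1 and Fibcd1, the CA3 marker Bok and the DG marker Prox1 in each of the 14 libraries, by region and treatment. CA1 dissociated replicate 3 had 13.3 CPM of Wfs1 and 206.1 CPM of Bok.

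Between CA1 and CA3, 15 genes were called, 1 higher and 14 lower in CA1 (edgeR). The higher gene was Lct, the lactase gene, which is on the list of granule cell markers (3.17 ± 0.49; 64.5 CPM in CA1, 7.46 in CA3 and 123.8 in DG). Among the lowest were Pcp4 (−5.50 ± 0.94), the lysophosphatidic acid receptor gene Lpar1 (−3.36 ± 0.58), the teneurin Tenm3 (−2.87 ± 0.51), Pde8a (−2.65 ± 0.52) and the protease gene Adamts4 (−2.58 ± 0.44). With 1 library left out, Lct was called in each of the 14 fits, Adamts4 in 11, Pcp4 and Lpar1 in 10, Tenm3 in 8 and Pde8a in 4. Pcp4 was at −4.30 and not called without CA3 control replicate 4, and Tenm3 was at −1.97 and not called without CA3 control replicate 1. Pcp4 is also on the list of CA2 markers, of which it was the 1 called gene among 7 (median −1.68, camera adjusted p = 0.000923, adjusted p = 0.273 with an estimated correlation). No CA1 marker was called (4 higher adjusted over the list alone; median 0.82, camera adjusted p = 2.39e-05, adjusted p = 0.503 with an estimated correlation), nor was any CA3 marker (1 lower adjusted over the list alone; median −1.08, camera adjusted p = 0.00289, adjusted p = 0.503 with an estimated correlation). Without CA1 dissociated replicate 3, 74 genes were called, and with the dissociated libraries alone 1.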

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

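Of the tests of explanations in this part, those on the glial lists against the astrocyte and endothelial lists, on thinned libraries and on the correlation of Pde6a, Igf2bp2, Stox2 and Gnaz were chosen only after the result was seen. Single libraries were examined for standing apart in 68 groups of libraries and values, of which 3 did, where chance gives about 3.4. A further 17 differences of the treatment effect between regions passed a test, but those of gene lists were not called with an estimated correlation (adjusted p of 0.799 or more).

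The first pattern is the joint rise of oligodendrocyte and microglia markers in dissociated tissue. In a linear model of region and treatment, used for the score differences with an SE below, the mean score of both lists was higher by 1.39 ± 0.28 (log2, SE) in all 14 libraries. Depth as the whole cause stayed open in the test set beforehand, because the rise without the 3 shallow libraries, 1.09 ± 0.30, did not exceed the bound of 0.5 by the 2 SE required, but a rise of 1.10 ± 0.25 in libraries thinned to 1 depth, tried afterwards and read against 0, argues against it. A lower share of neurons, which would raise astrocyte and endothelial markers alike, cannot be told apart, because the glial score rose by 1.34 ± 0.43 more than the mean of those lists in all libraries but by 0.53 ± 0.28, within 2 SE of 0, in thinned ones. More white matter in the dissociated pieces cannot be told apart for microglia, whose rise with the oligodendrocyte score as a covariate was 0.90 ± 0.52, within 2 SE of 0. For oligodendrocyte markers, more white matter or a shift of subregion was not tested. CA1 dissociated replicate 3 and CA3 dissociated replicate 4, which had few CA1 markers, had the highest oligodendrocyte scores of their regions (7.40 and 8.15). The other dissociated CA1 and CA3 libraries also scored above each control of their region, so these values do not settle it. A response of the cells to dissociation and selective survival or release of these cell types stay open and were not tested.

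The second pattern is the rise of mitochondrially encoded transcripts, 0.96 ± 0.23 (log2, SE) for the list's score. Without the 3 shallow libraries it was 1.04 ± 0.29, which again did not exceed the bound of 0.5 by the 2 SE required beforehand, and in the thinned libraries, tried afterwards and read against 0, it was 1.07 ± 0.29, which argues against depth as the whole cause. A shift of the cell mix toward glia cannot be told apart, because the rise with the mean glial score as a covariate was 0.69 ± 0.44. Loss of cytosolic RNA from damaged cells and a cellular response also stay open.

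The third pattern is that counts of Pde6a, Igf2bp2, Stox2 and Gnaz did not follow depth: the slope of log2 counts on log2 depth was −0.21, −0.09, 0.11 and 0.23, against a median of 1.05 over 6210 genes. Together they held 0.978% of the counts of CA1 control replicate 1, against 0.0368% to 0.351% in the other controls. In DG dissociated replicate 3 they held 11.1%, against 0.216% to 3.77% in the other dissociated libraries. Both libraries stood apart from their groups, but the genes had been picked for counts that do not follow depth, so this is no separate evidence. Reads added to each library independently of its own RNA cannot be told apart from other causes: with depth removed the 4 genes' counts went together (mean pairwise correlation 0.783, against a 95th percentile of 0.305 in 10000 random sets of 4 genes), but the genes were picked for this pattern. The folds of Igf2bp2 and Gnaz between treatments are open to the same doubt, and a biological cause of their covariation was not tested.

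The third library to stand apart was CA1 dissociated replicate 3, whose score of CA1 markers was 2.93 against 7.41 to 8.24 in the other 5 CA1 libraries. The median treatment difference was larger in CA1 than DG by 1.58 for inflammatory genes, 0.92 for nuclear oxidative phosphorylation genes, 1.04 for ribosomal protein genes, 1.78 for oligodendrocyte and 1.56 for microglia markers, and was −1.42 for CA1 markers. For CA3 minus DG it was −1.63 for CA1 markers. For CA1 minus CA3 it was 0.75 for inflammatory genes, 0.31 for oxidative phosphorylation genes, 0.43 for ribosomal protein genes, 0.61 for oligodendrocyte, 0.75 for microglia, −0.56 for astrocyte, 1.52 for endothelial, 0.65 for interneuron and 1.48 for CA2 markers. These were list tests by camera with the preset correlation, and none was called with an estimated correlation. The 1 gene whose treatment difference was called between 2 regions was Rps12-ps3, CA1 minus DG (fitted log2 difference 11.99, which is no bound because the dissociated DG libraries were at 0; edgeR adjusted p = 0.0254).

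Other splits of the libraries bore on the counts of calls. For dissociated vs control, 1 of 100 splits within regions drawn from 360, the real one, called 101 genes, and the highest of the others called 11. The share was thus under 0.05. For CA1 vs DG the real split called 530 genes and the highest of the other 99 called 348, and for CA1 vs CA3 15 and 12. The share was under 0.05 in both (1 of 100 splits each), but for CA1 vs CA3 the margin was small. The libraries come from 1 mouse and differ in depth, so these shares make chance less likely but do not exclude it. For CA3 vs DG (231 genes, highest other 60, 18 splits) and for treatment in CA1 (25 genes, highest other 1, 10 splits) the splits are too few for a share under 0.05.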

How the results depend on the processing

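All settings below were planned before the data were examined, except the fits without the 3 shallow libraries, the thinned libraries and the list test on count-based z-scores. The list test called 9 lists in the main setting and 6 to 12 in 7 alternatives, and 8 to 12 with each library left out. Oligodendrocyte, oligodendrocyte precursor, microglia, mitochondrial, immediate early and inflammatory lists were called with an estimated correlation, and astrocyte, ribosomal and red blood cell lists were not. Single genes were followed under DESeq2, RLE scaling, the replicate block within regions (treatment only), without the 3 shallow libraries and with each library left out. Lists were followed under the other list tests, RLE and upper-quartile scaling, that block and the same left-out fits. In these settings no named gene or list was called in the opposite direction, and in the others the direction of single genes and lists was not checked. Of the values of single genes under an alternative, 1609 kept their side of the threshold, 277 lost the call and 11 gained one, and 44 of the losses came without the 3 shallow libraries, where fewer samples are tested and several folds were smaller. Of 108 gene results, 57 kept their side of the threshold in each fit with 1 library left out.

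The counts of called genes depended on the test and filter, and where no reason is given the cause was not tested. In the order dissociated higher, dissociated lower, CA1 vs DG, CA3 vs DG, CA1 vs CA3, the main counts were 95, 6, 530, 231 and 15. DESeq2 gave 411, 67, 998, 499 and 63, limma-voom 332, 88, 1258, 447 and 44, no filter 275, 70, 900, 616 and 127, and an adjusted p under 0.1 gave 166, 21, 809, 396 and 25. For the interaction, CA1, CA3 and DG, the main counts were 0, 25, 0 and 21. DESeq2 gave 28, 206, 0 and 104, limma-voom 0, 172, 0 and 0, no filter 128, 271, 29 and 261, and an adjusted p under 0.1 gave 1, 44, 0 and 97. RLE scaling gave 154 higher genes, a mean of at least 5 CPM gave 16 genes in CA1, and the equal-weight mean of regions gave 22 lower genes. On log2(TPM + 1) there were 7 higher and 48 lower genes, and on log2(TPM + 0.1) 6 and 21. With control libraries alone CA3 vs DG gave 132 genes. With dissociated libraries alone there were 135 for CA1 vs DG, 118 for CA3 vs DG and 1 for CA1 vs CA3. With each region's libraries alone CA1 gave 68, CA3 2 and DG 0.

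Without the 3 shallow libraries the counts were 13 higher and 0 lower genes, 359 for CA3 vs DG, 62 for CA1 vs CA3, 2 for the interaction, 0 in CA1 and 417 in DG, of which 17 were among the main 21. The thinned libraries gave 10 higher and 0 lower genes, all 10 among the main 95. Lone samples in these fits are assumed to vary like the other groups.

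Over all genes, the deviations from the group means of libraries with 1 label number had correlations of −0.03, 0.01 and 0.02 in CA1, 0.07 and 0.07 in CA3 and −0.16 in DG. Of these libraries, 6 of 12 were closest to their own number. The 2 CA3 values are 1 measurement, because deviations in a group of 2 mirror each other. Scores of CA3 markers did go with the number, at 4.16 and 4.28 in CA3 replicates 1 and 5.96 and 6.48 in CA3 replicates 4. The check therefore cannot exclude that equal numbers mark pairs, and the main model does not use them. With the replicate block within regions there were 216 higher and 164 lower genes, and 361 in CA1 alone. Under it Gria2 (−0.89), Npas4 (−1.28), Homer1 (−1.03) and Ccl3 (1.60) and the heat shock, nuclear oxidative phosphorylation and CA3 lists gained a call, and Gdap1 (−0.98) and the red blood cell list lost it. With the replicate block shared across regions there were 281 genes for CA1 vs DG, 123 for CA3 vs DG and 27 for CA1 vs CA3.

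With 1 library left out, higher genes ranged from 38 to 205 (CA1 control 2 38, CA1 control 3 40, CA3 control 1 50, CA3 control 4 52, CA3 dissociated 4 42, DG dissociated 4 205). Lower genes ranged from 0 to 53, with 0 without CA1 control 3, CA3 control 1 or CA1 dissociated 2, 1 without CA1 control 2, CA3 dissociated 4 or DG dissociated 3, 2 without CA1 control 1, 3 without CA1 dissociated 1, 10 without DG control 2 and 53 without DG dissociated 4. CA1 vs DG ranged from 199 to 765 (CA1 control 1 337, CA1 control 2 327, CA1 control 3 324, DG control 3 199). CA3 vs DG ranged from 56 to 564 (CA3 control 1 114, CA3 control 4 147, DG control 2 564, DG control 3 56, CA3 dissociated 1 87, DG dissociated 4 116). CA1 vs CA3 ranged from 7 to 74 (CA1 control 2 7, CA1 dissociated 1 and CA3 dissociated 1 8 each, CA3 dissociated 4 9, DG dissociated 4 30, DG control 2 34, CA1 dissociated 3 74). The interaction ranged from 0 to 5, with 5 without DG dissociated 4 and 1 without DG control 2, CA1 dissociated 2 or CA1 dissociated 3. CA1 ranged from 0 to 110, with 0 without CA1 control 2, CA1 control 3 or CA1 dissociated 2, 7 without CA1 dissociated 3, 10 without CA1 control 1, 12 without CA3 control 1 or 4, 41 and 43 without DG dissociated 3 and 4, and 110 without CA1 dissociated 1. DG ranged from 1 to 70 (DG control 2 1, DG control 3 12, CA1 dissociated 2 13, DG dissociated 4 38, DG dissociated 3 59, CA1 dissociated 3 70), and CA3 stayed at 0. Restricting to protein-coding genes was not run, since all transcripts are coding. Depth limits DG most: its dissociated libraries hold 65887 and 598775 counts, so 0 counts allow 45.5 and 5.01 CPM there.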

Other observations

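Beyond the fixed lists, 50 of the 101 genes called between dissociated and control tissue were in no list. The genes in this paragraph were chosen after their values were seen, and no enrichment was tested among them. Higher in dissociated tissue were Olig2, a transcription factor gene of the oligodendrocyte lineage (log2 fold change 1.77 ± 0.36 SE), Bcas1 (1.62 ± 0.29) and the glial gap junction gene Gjc3 (1.71 ± 0.33). Plek, a protein kinase C substrate of blood cells, was higher by 1.96 ± 0.30 (37.0 CPM in control and 149.7 in dissociated libraries), and Unc93b1, a chaperone of toll-like receptors, by 1.92 ± 0.39. The cholesterol carrier gene Npc2 was higher by 1.69 ± 0.38, the lysosomal protease gene Ctsd by 0.95 ± 0.20, the integrin-binding Tln1 by 1.32 ± 0.23 and the prostaglandin D synthase gene Ptgds by 1.96 ± 0.41. Each of these was called by edgeR (adjusted p from 0.00213 for Plek to 0.0322 for Npc2).

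Across the 4291 genes with a mean of at least 50 CPM, the fold changes of dissociation in CA1 and CA3, which share no library, had a Pearson r of 0.63 and a Spearman rho of 0.55. CA1 and DG gave 0.05 and −0.01, and CA3 and DG 0.19 and 0.16. These are correlations across genes, which are not independent replicates, and the DG fold changes include a library of 65887 counts. CA1 dissociated replicate 3 and CA3 dissociated replicate 4 both had few CA1 markers (scores of 2.93 and 2.54) and high scores of CA3 markers (5.93 and 6.48), so a shift of subregion shared by both could add to the correlation of CA1 and CA3. Without both libraries, a choice made after the values were seen, r was 0.53 and rho 0.45, and without the CA3 one alone 0.48 and 0.40.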
